A study of Eragrostis tef with 16 samples.

How the data were processed

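Root and shoot samples of tef (Eragrostis tef, an allotetraploid cereal) grown with low or optimum calcium gave 16 libraries, 4 in each of 4 groups. The labels call the 4 libraries of a group replicates and do not say whether they came from separate plants, so every p-value measures only the spread between samples, which may be technical. The title of 1 library names both tissues. It was placed in the low-calcium shoot group as replicate 4 because its source name is shoot.

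The deposited file holds 2 blocks. Per the file headers, the first gives small RNA read counts (unit: other, whole-number reads per length class) for the 19 lengths from 17 to 35 nt, which is a part of each small RNA library and not its full depth. The second gives deposited log2 values for 5824 genes headed as target gene IDs, each with its best hit in Setaria (5405 genes), rice (126) or sorghum (75) and a description where one exists. A further 5634 listed IDs have no values. The columns of the second block were matched to libraries by tissue letter and by the number in header and title. The optimum-calcium columns of this block begin with a letter H that is not explained. That both blocks come from the same 16 libraries rests on this match. How the target genes were chosen, and the aligner, genome build and counting software, are not given in the sources used here, and no gene positions are given. No miRNA levels were in the file, so no miRNA was tested.

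The scale of the deposited log2 values was worked out from the values. In each library 2 to the power of the value, minus 1, was a whole multiple of 1 step for 100% of the 93184 values, with a tolerance of 0.1 of a step. The values are therefore log2 of scaled reads plus 1 as the authors deposited them, and the reads of each gene were recovered as whole numbers. The offset of 1 makes the fold changes of genes with few reads too small. Of the 5606 genes with a description, 3601 share it with another gene, as copies from the 2 subgenomes would, so the division of reads between near-identical copies is uncertain. 

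The planned analysis was for miRNA counts and named limma as the fallback for other values. The fallback was used: limma with an intensity trend on the deposited log2 values of all 16 libraries, 1 coefficient per group, no replicate term, and Benjamini-Hochberg adjustment over all 5824 genes with a threshold of 0.05. The contrasts were low minus optimum calcium in root and in shoot, the difference between these responses (root minus shoot), and root minus shoot at each calcium level. The overlap of the calcium responses was tested with Fisher's exact test, two-sided, against the 5824 genes. Word lists drawn from the descriptions were tested with camera (preset correlation 0.01) over 6 lists and both tissues, with camera at an estimated correlation and fry beside it. Read lengths, depth and list shares were compared by two-sided exact permutation tests of 4 against 4 libraries, where 70 assignments give 0.0286 as the smallest p. A comparison at this smallest p passes Benjamini-Hochberg correction only if most tests adjusted with it reach it too. Failing correction there does not show that the groups were alike.

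The groups, contrasts, tests, 6 lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, in each calcium contrast, the 12 genes with the largest rise and the 12 with the largest fall among those that passed with a mean of at least 10 CPM (reads scaled to library size). It adds 5 and 5 in each tissue contrast and the 6 smallest p-values of the difference between responses. From each list it takes up to 4 members that passed, by mean reads over all 16 libraries, or the 2 with the most where none passed. Lists for iron and zinc, cutin and wax, and low-oxygen markers were added after seeing the data.

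Alternatives were median-ratio size factors, scaling by the total of the listed genes, a filter of 10 CPM in at least 4 libraries, a pseudocount of 0.1, a replicate block, libraries of a single tissue, a log2 fold change of at least 1, and leaving out each library. Added after seeing the data were voom on the recovered reads, thinning to the smallest library, other length denominators, all 19 length classes, the overlap under each setting, the calcium transport share without its 1 or 2 members whose shoot share was lowered most, and shoot list shares without each library. The filter of 10 CPM removed none of the 5824 genes, so it tested nothing. On simulated data 100 genes were changed 2-fold and 100 changed 4-fold. The limma test called 54% and 88% of them in root and 61% and 85% in shoot. It called 0.124% and 0.196% of the unchanged genes. Each gene was drawn independently, so shifts shared by many genes of a library were not simulated and these rates need not hold here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.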

Results

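Reads on genes headed as target gene IDs, and the lengths of small RNA reads, were compared between tef roots and shoots grown with low or optimum calcium. Each group had 4 libraries. The header does not say what the genes are targets of. The assay behind the gene values is not given, so whether they count mRNA or small RNA reads on these genes is unknown, and rose and fell refer to these reads. Recovered gene reads were 2.80 ± 0.500 Mreads (megareads; SD, n = 4, range 2.32 to 3.44) in optimum-calcium root, 1.71 ± 0.360 Mreads (1.20 to 2.02) in low-calcium root, 2.70 ± 0.104 Mreads (2.63 to 2.85) in optimum-calcium shoot and 1.96 ± 0.158 Mreads (1.82 to 2.10) in low-calcium shoot. The 17 to 35 nt small RNA reads numbered 14.6 ± 4.22 Mreads, 7.12 ± 2.42 Mreads, 14.8 ± 6.75 Mreads and 13.1 ± 6.21 Mreads in the same order (SD, n = 4). Gene reads were fewer under low calcium in both tissues and small RNA reads were fewer in root. Each had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.0667 over 14 tests. None passed correction, which at this smallest p needs most of the 14 tests to reach it. The small RNA reads of shoot had an exact permutation p of 0.743. Spearman correlations across genes between replicates ranged from 0.886 to 0.984. Each of the 16 libraries correlated more with the other libraries of its labelled tissue (Spearman 0.857 to 0.982 across genes) than with the other tissue (0.391 to 0.552), the shoot library with the ambiguous title included.

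**Figure D1:**
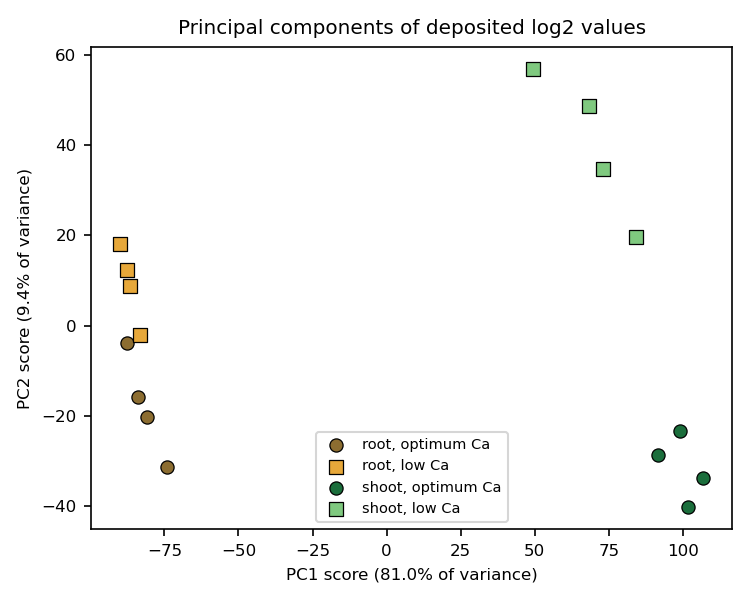
Scores of the 16 libraries on the first 2 principal components of the deposited log2 values, with the percent of variance on each axis; circles are optimum calcium and squares low calcium, brown and orange are root, greens are shoot. PC1 holds 81.0% of the variance and has root and shoot at opposite ends, and PC2 holds 9.39%, with the low-calcium libraries above the optimum-calcium ones of their tissue.

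In shoot, the genes with the largest rises under low calcium included several with roles in the cuticle. Both genes described as cytochrome P450 86A4, a family that hydroxylates fatty acids for cutin, rose by a log2 fold change of 7.31 (SE 0.47, Et_7A_053112, limma adjusted p 9.8e-08) and 6.70 (SE 0.52, Et_7B_055862, limma adjusted p 5.3e-07). The mean log2 value of Et_7A_053112 was 0.50 ± 0.58 under optimum and 7.81 ± 0.99 under low calcium (SD, n = 4). Summed over 4 libraries it had 2 reads under optimum and 887 under low calcium, a ratio per gene read of 610 (95% exact Clopper-Pearson interval 168 to 5041, counting error only). Long chain acyl-CoA synthetase 2 (Et_6B_048779) rose by 6.82 (2 and 667 reads, ratio 458, interval 126 to 3793), and 2 copies of BODYGUARD 3, which belongs to a family needed for the cuticle, rose by 6.09 (Et_2A_015401) and 5.99 (Et_2B_019607). A group 3 late embryogenesis abundant protein (Et_4A_034454, 7.16) and the sugar transporter SWEET4 (Et_1A_009171, 5.93) also rose. The 2 largest falls were those of ion transporters: cation/H+ antiporter 20 (Et_9A_063199) fell by 3.77 (SE 0.63, limma adjusted p 3.6e-04) and vacuolar cation/proton exchanger 1a, a calcium transporter of the vacuole membrane, fell by 2.55 (Et_3B_028509, SE 0.35, limma adjusted p 7.1e-05). The iron-regulating ubiquitin ligase BRUTUS (Et_9B_065009) fell by 2.01 and the calcium-binding protein CML36 (Et_6B_049755) by 1.85.

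In shoot 2292 of 5824 genes passed the limma test, 1075 higher and 1217 lower under low calcium, and 962 of them also changed at least 2-fold, 782 higher and 180 lower. The split into higher and lower rests on the scaling: 46.9% of calls were higher with the deposited scale, 59.4% with median-ratio size factors (1214 higher, 830 lower) and 72.9% with scaling by the total (1278 higher, 476 lower), as the median log2 change of all genes moved from -0.12 to 0.00 and 0.07. Without the library with the ambiguous title, low-calcium replicate 4, 1576 genes passed.

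Of 37 cell wall genes in shoot 22 rose, 1 fell and 14 did not pass (median 1.31, camera adjusted p 2.5e-07 in limma, adjusted p = 0.193 with an estimated correlation). These included cellulose synthase subunit 9 (Et_2A_018320, 2.68, and Et_2B_022375, 2.52) and a polygalacturonase (Et_2B_020416, 3.04), an enzyme that cleaves pectin. Of 70 oxidative stress genes 45 rose, 2 fell and 23 did not pass (median 1.47, camera adjusted p 1.2e-12 in limma, adjusted p = 0.0917 with an estimated correlation). Cationic peroxidase SPC4 (Et_7A_051522) rose by 3.52. Many members are class III peroxidases and laccases, which also act in lignin formation. Adjusted over the list alone, 22 cell wall genes rose and 1 fell, and 45 oxidative stress genes rose and 3 fell.

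Calcium sensing genes that passed in shoot were nearly all lower under low calcium. Of 38 calcium sensing genes 1 rose, 20 fell and 17 did not pass (median -0.48, camera adjusted p 0.00167 in limma, adjusted p = 0.113 with an estimated correlation). Adjusted over the list alone the counts were also 1 and 20. Calmodulin-binding protein 60 D (Et_7B_053843) fell by 0.62 and CBL-interacting protein kinase 9 (Et_4A_032628) by 0.96. The falls numbered 15 with median-ratio factors and 10 with scaling by the total. Of 14 calcium transport genes 1 rose, 4 fell and 9 did not pass, the same adjusted over the list alone, and the list did not pass (camera adjusted p 0.206, adjusted p = 0.413 with an estimated correlation), while fry, which does not compare it with other genes, gave an adjusted p of 0.0140 downward. Its falls included exchanger 1a and cyclic nucleotide-gated ion channel 17 (Et_6B_049571, -0.74). None of the 12 photosynthesis genes passed the limma test, where 2858 of all genes had an unadjusted p under 0.05 (median -0.23, camera adjusted p 0.695, adjusted p = 0.819 with an estimated correlation, 0 and 0 adjusted over the list alone). The 2 most abundant, both chlorophyll a-b binding protein 1, had log2 changes of -0.30 (Et_2B_022256) and -0.42 (Et_2A_014514). Of 94 transcription factors in families that conserved miRNAs target, 28 rose, 12 fell and 54 did not pass, with the same counts adjusted over the list alone (camera adjusted p 0.0312, adjusted p = 0.0403 with an estimated correlation). With scaling by the total 7 of them fell. Scarecrow-like protein 8 rose by 1.13 (Et_7B_055815, limma adjusted p 2.5e-04) and 0.65 (Et_7A_053059), while NAC domain protein 82 fell by 0.95 (Et_9B_064448) and 0.90 (Et_9A_061866), and auxin response factor 9 (Et_7A_051103) by 0.78. Without optimum-calcium shoot replicate 3 this list had an adjusted p of 0.0555.

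In root, named genes that rose included 2 WRKY76 genes and a peroxidase, and metal transporters went both ways. Transcription factor WRKY76 rose by 2.40 (Et_2A_016308, SE 0.44, limma adjusted p 0.00918) and 2.34 (Et_2B_020390), and peroxidase 70 (Et_1B_012523) rose by 2.36 (SE 0.41, limma adjusted p 0.00606). A monooxygenase described as acting on 4-hydroxyphenylacetaldehyde oxime (Et_4A_034368) rose by 3.61 (SE 0.67). Wall-associated receptor kinase-like 16 (Et_3B_028075) rose by 2.19. Alcohol dehydrogenase 2, an enzyme of fermentation, fell by 1.93 (Et_6A_047661, SE 0.25, limma adjusted p 9.4e-04). The metal-nicotianamine transporter YSL16 (Et_3B_031448) fell by 1.71 and ZINC INDUCED FACILITATOR-LIKE 1 (Et_6A_046738) by 1.58. The metal-nicotianamine transporter YSL12 (Et_7B_055138) rose by 1.09 in root (limma adjusted p 0.0137, 0.0530 without low-calcium root replicate 4) and by 0.81 in shoot (limma adjusted p 0.00875).

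**Figure D2:**
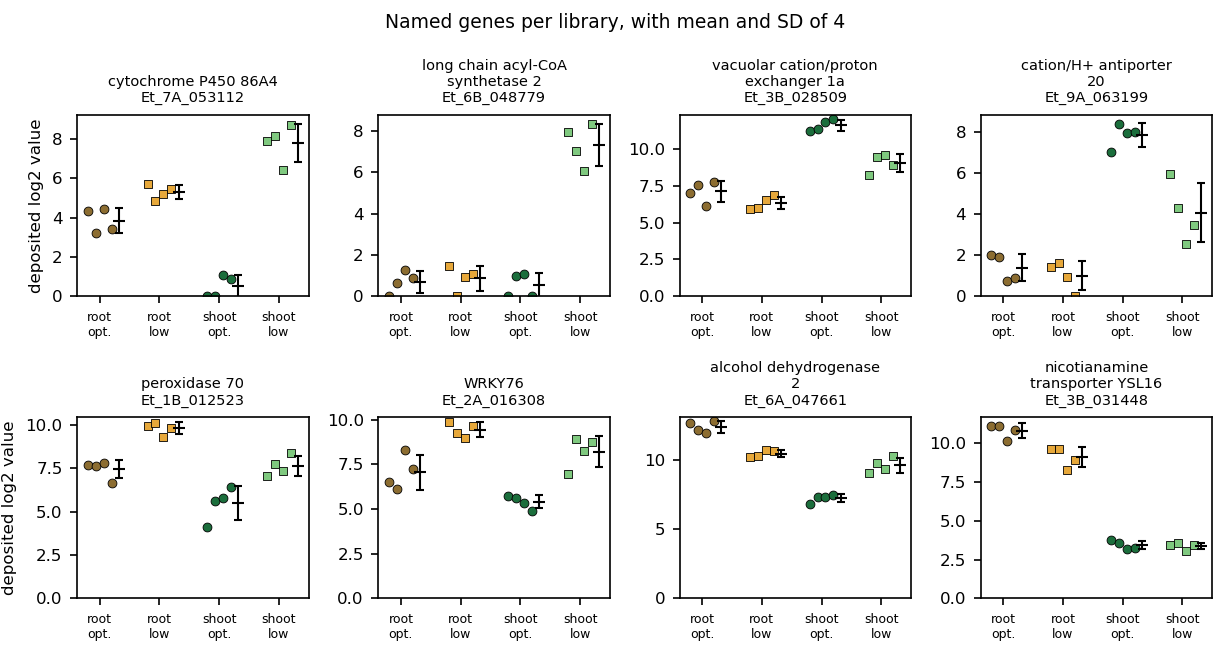
Deposited log2 value of 8 named genes in each library (points) with the mean and SD of 4 (bars) for root and shoot at optimum (opt.) and low calcium. Cytochrome P450 86A4 has a mean of 0.50 in optimum-calcium shoot and 7.81 in low-calcium shoot, and alcohol dehydrogenase 2 goes from 12.37 to 10.44 in root and from 7.24 to 9.60 in shoot.

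In root 485 of 5824 genes passed the limma test, 310 higher and 175 lower, and 228 of them changed at least 2-fold, 184 higher and 44 lower. With median-ratio factors 74.2% of 461 calls were higher, against 63.9%. The count moved with single libraries: without optimum-calcium root replicates 1, 2, 3 and 4 it was 167, 136, 816 and 109, and without low-calcium root replicates 1, 2, 3 and 4 it was 99, 88, 600 and 66. It was 831 with the root libraries alone and 271 with a replicate block added to these.

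Of 70 oxidative stress genes in root 12 rose, 0 fell and 58 did not pass (median 0.79, camera adjusted p 1.0e-06 in limma, adjusted p = 0.193 with an estimated correlation), and 20 rose and 1 fell adjusted over the list alone. These rises numbered 25 with the root libraries alone, 20 with voom, 6, 5 and 5 without optimum-calcium root replicates 1, 2 and 4, and 3, 4 and 4 without low-calcium root replicates 1, 2 and 4. Of the 94 transcription factors 11 rose, 0 fell and 83 did not pass (camera adjusted p 0.00929 in limma, adjusted p = 0.0212 with an estimated correlation), and 17 rose and 2 fell adjusted over the list alone. The rises among transcription factors numbered 20 with the root libraries alone, 19 with voom, 6, 5, 18 and 3 without optimum-calcium root replicates 1, 2, 3 and 4, and 3, 4 and 1 without low-calcium root replicates 1, 2 and 4. Scarecrow-like protein 8 rose by 0.89 (Et_7B_055815) and 0.93 (Et_7A_053059), with limma adjusted p 0.0505 and 0.0506 without low-calcium root replicate 4. Of 37 cell wall genes 1 rose and 2 fell, also adjusted over the list alone (median 0.61, camera adjusted p 0.0104, adjusted p = 0.430 with an estimated correlation). Cellulose synthase-like H1 (Et_1A_009508) fell by 1.42. The rises numbered 5 with voom, 6 without optimum-calcium root replicate 3, and 0 without any 1 of optimum-calcium root replicates 1, 2 and 4 and low-calcium root replicates 1, 2 and 4. Without optimum-calcium root replicate 4 the cell wall list had an adjusted p of 0.210. Of 12 photosynthesis genes 1 rose and 0 fell, 2 and 0 adjusted over the list alone (camera adjusted p 0.0497, adjusted p = 0.351 with an estimated correlation). This call was lost with median-ratio factors (0.0549), with a replicate block (0.0597), and without optimum-calcium root replicates 1 (0.0541) and 3 (0.201) and low-calcium root replicates 1 (0.0665) and 3 (0.0816). Of 38 calcium sensing genes 0 rose and 2 fell, also adjusted over the list alone (camera adjusted p 0.0850, adjusted p = 0.351 with an estimated correlation). CBL-interacting protein kinase 9 (Et_4A_032628) fell by 1.36 and a second gene of that name (Et_4B_036730) by 1.30. The latter did not pass without optimum-calcium root replicate 4 (adjusted p 0.0501), without low-calcium root replicates 1 (0.0677), 2 (0.0577) and 4 (0.0596) or with voom (0.132), where the falls numbered 1, and they numbered 5 without optimum-calcium root replicate 3. None of 14 calcium transport genes passed the limma test, over all genes or adjusted over the list alone, where 1648 of all genes had an unadjusted p under 0.05 (camera adjusted p 0.445, adjusted p = 0.581 with an estimated correlation). Over the 16 libraries of both tissues, the members with the most reads were calcium-transporting ATPase 10 (Et_4B_039870) and exchanger 1a (Et_3B_028509). Their log2 changes in root were 0.00 (SE 0.36) and -0.79 (SE 0.35). In root alone other members, such as annexin-like protein RJ4 (Et_9B_064255), had more reads than exchanger 1a.

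**Figure D3:**
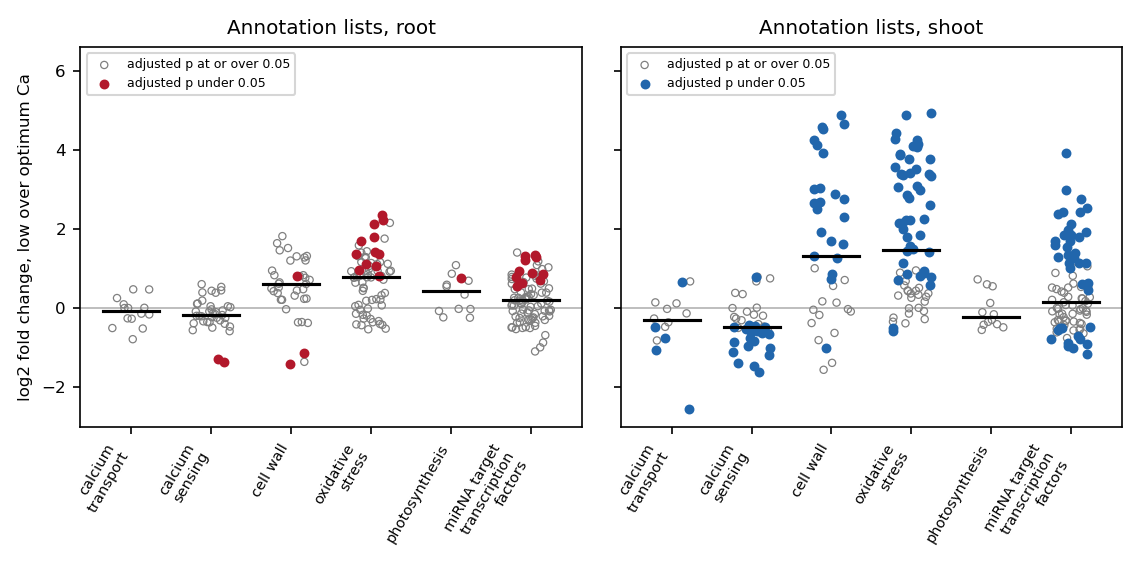
Log2 fold change, low over optimum calcium, of each gene of the 6 fixed lists in root and shoot; filled points have a limma adjusted p under 0.05, open points do not, and black bars are list medians. In shoot the medians of the cell wall and oxidative stress lists are 1.31 and 1.47 and that of calcium sensing is -0.48 (deposited scale; the signs are the same with both other scalings).

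The root and shoot responses overlapped. Of genes called in both tissues, 136 were higher in both (57.2 expected, two-sided Fisher's exact p 2.1e-26) and 98 lower in both (36.6 expected, p 4.6e-25), while 16 went opposite ways (97.1 expected). Genes are not independent replicates, and the contrasts of both tissues share an estimate of spread per gene. The library numbers in the titles place all low-calcium libraries before all optimum-calcium ones, in both tissues. Whether this order followed the processing is not given. A difference that followed it would be shared by root and shoot and cannot be told apart from calcium. The size of the overlap follows the root count: the 234 genes with the same direction (93.8 expected) became 73, 57, 424 and 41 without optimum-calcium root replicates 1, 2, 3 and 4 (30.5, 25.2, 171 and 21.1 expected). Without low-calcium root replicates 1, 2 and 4 they were 42, 39 and 25 (18.9, 16.2 and 12.2 expected), and 143 with reads thinned to the smallest library (58.7 expected). The responses differed between tissues for 431 genes by the limma test of the difference, 106 with a more positive response in root and 325 with a more positive response in shoot. Alcohol dehydrogenase 2 (Et_6A_047661) fell in root and rose by 2.37 in shoot, a difference of -4.30 (SE 0.35, limma adjusted p 9.0e-06). The wax ester synthase WSD1 (Et_4B_036831, -2.49), respiratory burst oxidase B (Et_10B_003796, -5.37), BODYGUARD 3 (Et_2A_015401, -4.59) and cytochrome P450 86A4 (Et_7A_053112, -5.84) had a more positive response in shoot. The count was 268 without optimum-calcium root replicate 1, 276 and 261 without low-calcium root replicates 2 and 4, 704 and 271 without low-calcium shoot replicates 3 and 4, and 196 with voom. With scaling by the total, 14.1% of calls had the more positive response in root, against 24.6%, as the median of all genes moved from 0.07 to -0.12.

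Roots and shoots differed in 3878 genes under optimum calcium (1916 higher in root, 1962 lower) and 3311 under low calcium (1655 higher, 1656 lower) by limma. Under optimum calcium YSL16 (Et_3B_031448) was higher in root by 7.37 (SE 0.29) and nicotianamine synthase 2 (Et_4A_031983), which makes a metal chelator, by 7.24 (SE 0.48). Among the genes higher in shoot, the root minus shoot change was -8.66 (SE 0.28) for chloroplast glyceraldehyde-3-phosphate dehydrogenase A (Et_7B_053948) and, under low calcium, -8.09 (SE 0.27) for protochlorophyllide reductase (Et_7B_055072). Scaling by the total gave 67.4% of 4137 calls higher in root under optimum calcium and 63.3% of 3537 under low calcium, as the median of all genes moved from -0.04 to 0.41 and from 0.01 to 0.27.

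As a share of each library's gene reads, cell wall genes took 0.244% ± 0.0497 of optimum-calcium and 0.787% ± 0.246 of low-calcium shoot reads, and oxidative stress genes took 0.707% ± 0.170 and 1.46% ± 0.440 (SD, n = 4). Calcium transport genes took 0.319% ± 0.0725 and 0.197% ± 0.0241 of shoot reads, and calcium sensing genes 0.963% ± 0.150 and 0.693% ± 0.0240. In root, oxidative stress genes took 2.17% ± 0.274 and 3.50% ± 0.438. Each of these 5 comparisons had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.0686 over 12 tests. None passed correction, which at this smallest p needs most of the 12 tests to reach it, however large a difference is. Of the calcium transport share, exchanger 1a (Et_3B_028509) made up 0.123% and 0.0245%, and without it, a choice made after seeing the data, the list took 0.196% ± 0.0663 and 0.172% ± 0.0246 (exact permutation p 0.714). The next largest difference was that of calcium-transporting ATPase 10 (Et_4B_039870, 0.0687% and 0.0374%), which did not pass in shoot (limma adjusted p 0.0832) and came from 1 library. Optimum-calcium shoot replicate 3 had a log2 value of 12.15 against 9.92 to 10.07 in the other 3, and without it the optimum-calcium share of this gene was 0.0407% ± 0.00342 (SD, n = 3). Without both genes the list took 0.128% ± 0.0130 and 0.135% ± 0.0189 (exact permutation p 0.571). Photosynthesis genes took 9.89% ± 1.02 and 8.94% ± 1.45 of shoot reads (exact permutation p 0.343).

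Small RNA reads of 24 nt, the class of siRNAs that direct DNA methylation in plants, made up 10.1% ± 1.21 of optimum-calcium and 8.83% ± 0.235 of low-calcium root reads (SD, n = 4, exact permutation p 0.143). Those of 21 nt, the usual length of plant miRNAs, made up 7.42% ± 1.03 and 5.87% ± 0.174 in root. The 20 nt class made up 5.12% ± 0.359 and 4.30% ± 0.191, and the 22 nt class 5.38% ± 0.366 and 4.59% ± 0.228. These 3 root comparisons had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.0667 over 14 tests. None passed correction, which at this smallest p needs most of the 14 tests to reach it. The lower percent was not particular to the 20 to 22 nt classes: over all 19 lengths, tested after seeing the data, the root classes from 17 to 22 nt were lower and those from 26 to 32 nt higher under low calcium, each with an exact permutation p of 0.0286 and an adjusted p of 0.0679 over 38 tests. The 17 nt class made up 4.87% ± 0.577 and 3.79% ± 0.207, and the 30 nt class 4.56% ± 0.747 and 6.46% ± 0.488. In shoot the same tests gave this p and adjusted p for higher percents at 31 nt (3.90% ± 0.265 and 5.97% ± 1.32) and 32 nt (3.69% ± 0.184 and 5.50% ± 1.22) and a lower percent at 35 nt (13.7% ± 3.37 and 7.95% ± 0.861). The shoot 21 nt class made up 6.65% ± 0.853 and 6.46% ± 0.439 (exact permutation p 0.686) and the 24 nt class 11.1% ± 0.982 and 11.9% ± 2.78 (exact permutation p 0.629). The shoot 21 nt result depends on the denominator. Of 18 to 30 nt reads, a denominator chosen after seeing the data, this class made up 11.5% ± 0.645 and 10.5% ± 0.0714 in shoot. That comparison had an exact permutation p of 0.0286 and an adjusted p of 0.0714. Exact permutation tests of the difference between tissues were run only for depth and the 20 to 24 nt classes, as percent of 17 to 35 nt reads. They had adjusted p of at least 0.293.

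**Figure D4:**
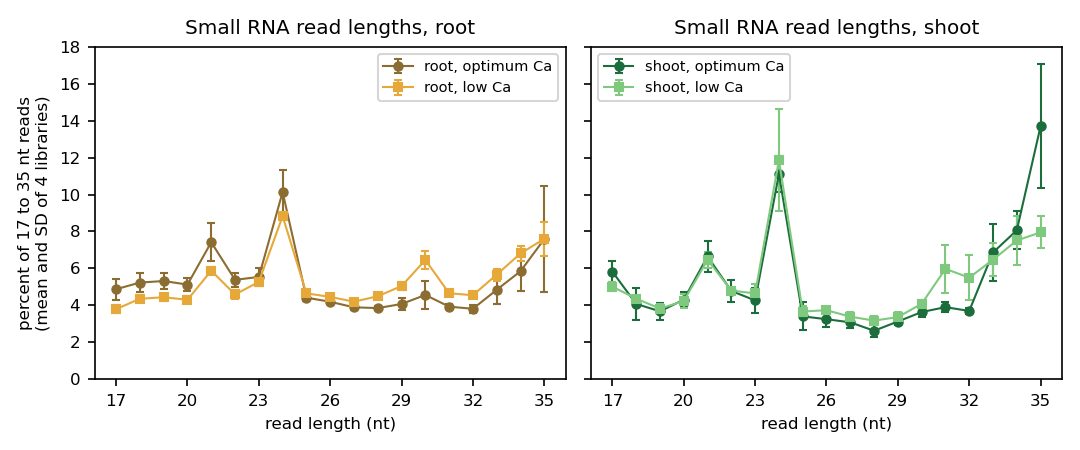
Percent of 17 to 35 nt small RNA reads at each length in root and shoot, as mean and SD of 4 libraries for optimum calcium (circles) and low calcium (squares). The 24 nt class is at 10.1% and 8.83% in root and 11.1% and 11.9% in shoot, and at 35 nt optimum-calcium shoot is at 13.7% and low-calcium shoot at 7.95%.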

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

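No test of an explanation given here was part of the fixed plan. The bound for each was written before its result was seen, except for leaving out the shoot library with the ambiguous title as a test of a wrong label. In 15 of 325 groups of 4 libraries, 1 library lay far from the other 3 by Dixon's ratio of gap to range (above its critical value for 4 values), where chance gives about 1 in 20 groups, or 16.25. Optimum-calcium root replicate 4 stood apart in Et_1B_012523 (0.862). Optimum-calcium root replicate 3 stood apart in Et_4A_035097 (0.865) and Et_1B_014354 (0.864). Low-calcium root replicate 3 stood apart in Et_1A_007077 (0.908). Low-calcium shoot replicate 3 stood apart in Et_2B_019607 (0.830), Et_2A_018320 (0.885) and Et_2B_022375 (0.899). Optimum-calcium shoot replicate 3 stood apart in Et_3B_030422 (0.919), Et_7B_055014 (0.909) and Et_8A_058293 (0.898). Optimum-calcium shoot replicate 1 stood apart in Et_8B_059519 (1), Et_10A_001881 (0.878) and Et_6A_047661 (0.841). Low-calcium shoot replicate 1 stood apart in Et_6A_047379 (0.902). Some of these flags lie near the floor, where the rate of 1 in 20 need not hold. Et_8B_059519 had 1 read over the 4 libraries. The log2 values were 0 against 0.89 to 0.99 for Et_8A_058293, 2.13 against 0.89 to 0.99 for Et_3B_030422 and 0 against 1.69 to 1.87 for Et_6A_047379. Outside the 325 groups, Et_4B_039870 was named in root only, and its log2 value in optimum-calcium shoot replicate 3 was 12.15 against 9.92 to 10.07 in the other 3. The percent of 24 nt reads in optimum-calcium root replicate 2 was 8.34, against 10.5 to 10.9 in the other 3 (ratio 0.844).

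The response to low calcium differed between root and shoot for 431 genes in all by limma, and for 39 of the 119 named genes; values are the log2 response in root minus that in shoot. The response was more positive in root for Et_4A_034823 (3.60), Et_9A_063199 (3.39), Et_3B_028310 (2.90), Et_1A_007903 (2.61), Et_3B_028075 (2.28), Et_4A_033729 (2.17), Et_6B_049049 (1.99), Et_3B_028509 (1.76), Et_9A_061766 (1.60) and Et_7A_051103 (0.90). The response was more positive in shoot for Et_6B_048779 (-6.64), Et_4A_034454 (-6.60), Et_3B_030422 (-6.01), Et_1A_009171 (-5.87), Et_7A_053112 (-5.84), Et_7B_055862 (-5.56), Et_10B_003796 (-5.37), Et_3B_028344 (-5.30), Et_7B_055014 (-4.96) and Et_2B_021779 (-4.89). Further differences of this sign were those of Et_4A_032822 (-4.87), Et_2A_015401 (-4.59), Et_1A_007077 (-4.48), Et_2A_016645 (-4.48), Et_2B_019607 (-4.33), Et_6A_047661 (-4.30), Et_8B_059519 (-4.25), Et_2A_016216 (-3.89), Et_2B_021290 (-3.29) and Et_2B_021274 (-2.99). Smaller ones were those of Et_7A_050900 (-2.72), Et_4B_037022 (-2.72), Et_4B_036831 (-2.49), Et_3A_024347 (-2.41), Et_2B_020416 (-2.39), Et_1A_008197 (-2.09), Et_3B_030041 (-2.01), Et_6A_046738 (-1.94) and Et_3B_031448 (-1.65). Shuffling calcium labels within tissues gave as many genes in 3 of 100 regroupings, the real one included (431 genes, highest other 506). This share is under the threshold of 0.05, but another regrouping called more, so chance is not excluded for this count.

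Low-calcium shoot libraries lay closer to root libraries than optimum-calcium ones did, with a mean Spearman correlation with root across genes of 0.453 to 0.536 against 0.378 to 0.455, a gap of 0.0662. Root material in these libraries is argued against by root-marker genes, which are abundant in root and nearly absent in optimum-calcium shoot. The 100 most abundant reached a median 0.745% of their root level, while 794 raised genes reached 44.0%. The raised genes were picked because they rose in shoot and are higher in root, so the argument rests on the markers. Fewer reads are argued against, since the gap was 0.0667 after thinning to 1 depth, and so is a single wrong label, since it was 0.0476 without low-calcium shoot replicate 4. A shift of shoot expression under low calcium may be the cause, as a hypothesis found and tested on the same data, and a difference between plants or harvests that followed the groups was not tested.

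The shoot count of 2292 genes became 2088 after thinning all libraries to the smallest (2022 to 2106 over 21 draws), which argues against fewer reads in low-calcium libraries as its source. No other split of the 8 shoot libraries into 4 and 4 called a gene. With the shoot libraries alone, 1747 genes against 0 were called, so 1 of 35 splits, the real one, reached this count. That is the smallest share these splits allow, so chance is made unlikely but not excluded. Nor can the splits tell calcium from another difference between the groups. The optimum-calcium tissue contrast (3769 against 0) and the low-calcium one (3254 against 0) were each matched by 1 of 35 splits, the real one.

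The root count of 485 became 331 after thinning (276 to 355 over 21 draws). The median draw lies just above the bound set for excluding fewer reads as the source, but the draws fall on both sides of it, and none reached the bound that would bear this source out. At equal depth 276 genes or more were called in every draw, which argues against unequal reads as the source of the whole count. For the remainder of the count, calcium and depth cannot be told apart. With the root libraries alone 831 genes were called and 1 of 35 splits reached this, the real one. This is the smallest share that 35 splits can give, so chance is made unlikely but not excluded. The highest other split called 595 genes and grouped low-calcium replicates 1, 2 and 4 with optimum-calcium replicate 3, so replicate 3 of each group changed places. The count of 485 was 816 without optimum-calcium replicate 3 and 600 without low-calcium replicate 3, while it fell to between 66 and 167 without any 1 of the other 6 root libraries.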

How the results depend on the processing

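Voom, thinning, other length denominators and the settings of the overlap were chosen after seeing the data. Not run, because the file held no miRNA counts, were TMM with edgeR, DESeq2 (also for the overlap), merging of duplicate sequences, miRNA family sums, removal of tRNA and rRNA entries, and the percent of distinct sequences. The cause of each change below was not tested, except that a fold threshold calls fewer genes by construction. A log2 fold change of at least 1 gave 228 genes in root and 962 in shoot. Root gave 831 genes with only the root libraries and 271 with a replicate block as well. The difference between responses gave 196 genes with voom. An unadjusted p under 0.05 gave an overlap of 899 genes (402 expected) and thinned reads one of 143. Camera with an estimated correlation called 1 list in root and 1 in shoot, and fry 2 in root and 5 in shoot, against 4 and 4 with the preset correlation. Leaving out each library gave 66 to 816 genes in root, 1576 to 2547 in shoot, 261 to 704 for the difference, 25 to 424 for the overlap, 3663 to 3906 and 3027 to 3406 for the tissues, and 3 to 4 lists in each tissue.

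With 18 to 30 nt reads as denominator, low minus optimum in shoot turned negative for the percent at 22 nt (-0.418) and 24 nt (-0.123). The photosynthesis list in shoot turned upward without low-calcium replicate 4 (adjusted p 0.845; range over leave-outs 0.520 to 0.858). Calcium-transporting ATPase 10 (Et_4B_039870) in root, at 0.00 and not called, turned negative in 7 settings: scaling by the total (-0.007717), voom (-0.001143), thinning (-0.02497), without optimum-calcium root replicate 2 (-0.004478) or 4 (-0.02759), and without low-calcium root replicate 3 (-0.06021) or 4 (-0.03466), with leave-outs from -0.06021 to 0.0756. Of 3173 comparisons of 129 named gene results, 2872 kept their direction and side of the threshold, 293 lost the call in the same direction, 1 gained it and these 7 turned. Of 47 root results 32 lost the call at least once, and of 56 shoot results 17, while the 6 of the difference and the 10 of each tissue contrast did not. The filter of 10 CPM removed no gene, and without its comparisons 2743 of 3044 were kept. Leaving out a library from outside a contrast, adding a replicate block or fitting a tissue alone cannot change its log2 change. Only the adjusted p can move in these settings, so the counts overstate how stable the directions are. Of 252 list comparisons, which hold none of this filter, 231 were kept, but 12 of the 13 lists called lost the call at least once.

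Replicate numbers gave no clear sign of pairing. After removing group means, correlations of same-numbered low and optimum libraries ran from -0.405 to 0.0808 in root and -0.0517 to 0.247 in shoot. Those of same-numbered root and shoot libraries at the same calcium level ran from -0.205 to 0.302. In all, 6 libraries were closest to their own number. With 4 libraries per group these values cannot exclude pairing, and the contrasts between tissues take root and shoot libraries as independent. A replicate block gave 363 genes in root, 2219 in shoot and 426 for the difference. The smallest library, in low-calcium root, has 1.20 Mreads of genes, and how calls depend on the reads of a gene was not tested.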

Other observations

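The lists of other gene groups were chosen after seeing the data, and none passed in either tissue with an estimated correlation. Of 31 cutin and wax genes 16 rose and 0 fell in shoot, 17 and 0 adjusted over the list alone (camera adjusted p 1.5e-09 in limma, adjusted p = 0.0868 with an estimated correlation), among them 3-ketoacyl-CoA synthase 5 (Et_1B_014244, 2.64, and Et_3A_026712, 1.73), which elongates fatty acids. In root 6 rose and 0 fell, 9 and 0 adjusted over the list alone (camera adjusted p 1.8e-04, adjusted p = 0.144 with an estimated correlation), with ECERIFERUM 26-like (Et_7B_054727) up by 1.79. The root count was 3, 1, 12 and 1 without optimum-calcium root replicates 1, 2, 3 and 4 and 1 without each of low-calcium root replicates 1, 2 and 4. Of 22 iron and zinc genes 1 rose and 4 fell in root, 3 and 11 adjusted over the list alone, and 1 and 7 over all genes with scaling by the total (camera adjusted p 0.00313, adjusted p = 0.256 with an estimated correlation, 0.0573 without low-calcium root replicate 3), with BRUTUS (Et_9A_062429) down by 1.48 in root, and 1 rose and 3 fell in shoot, 1 and 2 adjusted over the list alone (camera adjusted p 0.442, adjusted p = 0.748 with an estimated correlation). These lists were picked from the same values and are not independent evidence of their direction.

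Of 8 low-oxygen markers 0 rose and 2 fell in root, 0 and 3 adjusted over the list alone (camera adjusted p 0.00667, adjusted p = 0.144 with an estimated correlation), and 5 rose and 0 fell in shoot, 6 and 0 adjusted over the list alone (camera adjusted p 8.6e-04, adjusted p = 0.0874 with an estimated correlation). Of the 2 root falls, that of non-symbiotic hemoglobin (Et_1A_007077, -2.10, limma adjusted p 0.0448) was lost without any 1 of the 8 root libraries (adjusted p 0.0577 to 0.124), without optimum-calcium shoot replicate 2 (0.0548), with median-ratio factors (0.0542) and with the root libraries alone and a replicate block (0.0502), leaving 1. The response differed between tissues for 6 of the 8 by limma. Sucrose synthase 2 rose in shoot by 4.03 (Et_4A_032822) and 2.01 (Et_4B_037022), with root changes of -0.84 and -0.71 that did not pass. As a share of gene reads these markers took 0.993% ± 0.257 and 0.453% ± 0.0297 in root and 0.0720% ± 0.0190 and 0.408% ± 0.265 in shoot (SD, n = 4, optimum then low calcium, each exact permutation p 0.0286, adjusted p 0.0571).

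Of the 1075 genes that rose in shoot under low calcium, 794 were higher in root than in shoot under optimum calcium (354 expected). With different optimum-calcium shoot libraries on each side, 505 to 656 were (205 to 281 expected), and with the tissue difference under low calcium 503 were (305 expected). The expected counts take both sets as independent. Each listed gene reached a log2 value of at least 6.11 in some library. A gene low in all optimum-calcium shoot libraries is therefore listed only if it is high in root or in low-calcium shoot. Using different shoot libraries on each side does not remove this selection. The excess over the expected counts cannot be told apart from it, so no conclusion is drawn.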
